A study of Zea mays with 12 samples.

How the data were processed

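RNA of 12 maize samples was sequenced, as mRNA by the sample titles, per the labels' protocols after extraction with a plant RNA kit and standard Illumina library preparation. The samples form 4 groups of 3, Sdw3 and N18 in the developing internode between leaf 7 and leaf 8 and in the ligular region of leaf 8 and leaf 9, at the V7 stage. The labels do not say whether the 3 replicates of a group were separate plants, so the p-values measure spread between samples of unknown independence. Reads were processed with CASAVA 1.8, bcl2fastq, TopHat2 2.1.0 and Cufflinks on the maize build B73 RefGen_v3, per the submitters' processing notes. Which Cufflinks program made the tables, its version, its normalization between libraries and the annotation release are not given in the sources used here.

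Each of the 2 tissues has 1 table of 39514 genes. The authors gave each gene an FPKM per genotype, combined over the libraries; the unit is taken from Cufflinks being named in the submitters' processing notes and from the column layout, since no column header names it. The log2 fold change is the authors' log2 of the Sdw3 to the N18 value, per the file headers, with no pseudocount, and it was recomputed here from the 2 FPKM values. The score is the authors' test statistic, whose sign is opposite to the log2 column. The p-value and q-value (adjusted p) of each gene were computed by the authors between the genotypes within a tissue, per the file headers. Adjusting the p-values by Benjamini-Hochberg over the tested genes gave the deposited q-values within 5.3e-07, and the authors' significance mark was equal to a q-value under 0.05 for every gene. FPKM sums were 765530 (Sdw3) and 734039 (N18) in the internode and 826583 and 817741 in the ligular region. The 10 most abundant genes held 7.01% and 3.70% of the internode sums and 7.66% and 6.59% of the ligular sums. A single short gene model that the authors did not test, AC233788.2_FG002, held 3.52% of the Sdw3 internode sum and is listed at 0 in N18; without it the 10 most abundant genes held 3.87% of the Sdw3 internode sum and 6.29% of the Sdw3 ligular sum. Counts per library are not in the files, so the depth and the spread between replicates are unknown, and no interval or detection limit is given.

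The planned tests needed 1 value per library and could not be run as written. Those were a model fitted across all genes on log2(FPKM + 1) in each tissue, the replicate block, the leave-one-out fits, library weights, set tests with a preset or estimated correlation between genes, and other splits of the samples. In their place the authors' test was used: a gene is called at an adjusted p under 0.05 in the authors' deposited table, over 21131 tested genes in the internode and 22721 in the ligular region, with the authors' own choice of tested genes. The condition that the replicates of the genotypes do not overlap, part of the planned rule for named genes, could not be applied.

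To compare the tissues, an approximate standard error of each log2 ratio was taken as the ratio of the log2 fold change to the authors' score. It was divided by the median ratio of the normal quantile of the authors' p-value to the score (1.74 over 18834 genes in the internode, 1.71 over 18675 genes in the ligular region). A normal test with this standard error gave the same call as the authors for 99.1% and 98.3% of genes. The factor was fitted to the authors' p-values, so this share is no independent check of it. The difference between the tissues was tested as a normal deviate with Benjamini-Hochberg adjustment over 20070 genes. On simulated data with 200 changed genes this test recovered 16.5% of 1.5-fold, 75.5% of 2-fold and 95.5% of 4-fold differences, and 2.9%, 1.3% and 6.4% of the genes it passed were unchanged ones. The simulated values were drawn with the same standard errors that the test used. The low shares of unchanged genes therefore follow from the simulation and do not show that the standard errors are right. Overlap between tissues was tested over the 20099 genes tested in both by Fisher's exact test (two-sided).

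Gene lists were named before the data were examined: gibberellin, brassinosteroid, auxin, cytokinin, ethylene, abscisic acid, jasmonate, cell wall loosening, cellulose synthesis, lignin, cell cycle, histone, cytoskeleton, growth-regulating factor, ligule and leaf patterning, homeobox leucine zipper, photosynthesis, epidermis and wax, floral MADS-box, phloem and sugar, ribosomal protein, heat shock, defence and aquaporin genes. Their members were matched by gene name and synonym, with patterns written after the layout of the files had been seen but before any gene's values were read. The 2 planned auxin lists were merged, the gibberellin catabolism and transposon lists had no member by name, and the gibberellin response list (D8 and d9) had too few members for a test. A list of organ-size genes (CNR and ARGOS families) was added after the files had been seen. Added lists of microRNA precursors and of endosperm storage proteins were left out, because their name patterns took in other genes. Each list with at least 5 tested members was given the median difference of log2(FPKM + 1), set against 10000 random gene lists of the same size matched on 10 strata of expression, as a two-sided permutation test adjusted by Benjamini-Hochberg over the lists of a tissue. Of 100 simulated lists of 30 genes without a shift, 7 fell outside the central 95% of random lists, and all 100 did so with a shift of 0.5. Gene names came from a reference table of a later maize assembly: 18962 of 39514 identifiers matched, 517 of them to several entries and so left unnamed, and 2667 had an informative name. In the files 2215 genes share a locus with another gene.

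Named genes were chosen by a rule written before the data were examined. It takes, per tissue, the 10 called genes with the largest increase and the 10 with the largest decrease that have a name and reach an FPKM of 5 in the higher genotype. It adds up to 4 called members of each list with the smallest adjusted p, ties broken by the size of the change, the 5 genes with the largest difference between tissues in each direction, the 5 with the largest shared change in each direction, and the named members of the ligule and leaf patterning, gibberellin and brassinosteroid lists. The rule took 222 genes, of which 99 are named here; which of them to name was chosen after the values were seen. Genes listed at 0 in both tissues in 1 genotype and the positions of shared calls were looked at only after the values had been seen. Intervals of medians over the genes of a chromosome stretch (95%) are from order statistics, with genes taken as independent. Alternatives tried were other pseudocounts, filters on low values, scalings, thresholds, standard errors, and leaving out genes that share a locus. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.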

Results

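Transcripts of maize (Zea mays) carrying the Sdw3 mutation were compared with those of N18, the line the labels give as the comparison, in 2 growing tissues. The tissues were the developing internode between leaf 7 and leaf 8, which is the stem segment that elongates there, and the ligular region of leaf 8 and leaf 9, the zone at the base of the blade where the ligule forms. Plants were at the V7 vegetative stage, and each of the 4 combinations of tissue and genotype had 3 libraries by the labels, 12 in all. The deposited tables hold 1 combined FPKM (a fragment count scaled to transcript length and library size) per gene, tissue and genotype, so no spread between libraries can be given beside a level, and the read depth of each library is unknown. Of 39514 genes, 20766 reached an FPKM of 1 in the Sdw3 internode, 20632 in the N18 internode, 22094 in the Sdw3 ligular region and 21876 in the N18 ligular region. A gene is called higher or lower below when its adjusted p in the authors' deposited table is under 0.05, and every fold is the ratio of the authors' 2 combined FPKM values. Positions are on B73 RefGen_v3, as the files give them, and refer to whole gene loci.

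The first comparison asked which genes differ between Sdw3 and N18 in the developing internode. Growth-regulating factors, transcription factors that act with GIF partners in organ growth, were lower in Sdw3: 12 of the 17 members tested were called lower, 0 higher and 5 not called. GRF9 (GRMZM2G124566) was listed at an FPKM of 2.47 in Sdw3 and 8.68 in N18, 3.51-fold lower, and GRF2 (GRMZM2G099862) at 7.51 and 17.8, 2.38-fold lower. The SBP-box genes ub3 and ub2, known for limiting the number of kernel rows of the ear, were 3.46-fold and 2.54-fold lower. Of 12 organ-size genes of the CNR and ARGOS families tested, 6 were called higher, 1 lower and 5 not called; ZAR1 was at 15.1 in Sdw3 against 0.219 in N18, 68.7-fold higher.

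In total, 2389 of 21131 internode genes tested were called in the authors' deposited table, 1383 higher and 1006 lower in Sdw3, and 336 of the higher and 126 of the lower genes changed at least 2-fold. The median fold among called genes was 1.49. The smallest adjusted p in that internode table is 0.00109, shared by 970 genes, and each gene named in this and the next 2 paragraphs as called has that value in the authors' deposited table unless another is given. Among called genes with a name and an FPKM of at least 5 in the higher genotype, the largest increases, besides ZAR1 (GRMZM2G446201; chromosome 10, 119433275 to 119435009), began with AAE (GRMZM2G074759; chromosome 10, 148065470 to 148067620), an acyl-activating enzyme gene also named o7, at 5.98 against 0.142. In the authors' deposited table the adjusted p was 0.0102 for ZAR1 and 0.0284 for AAE. Both folds rest on an N18 level near 0: with a pseudocount of 1 the log2 ratio was 3.72 in place of 6.10 for ZAR1 and 2.61 in place of 5.40 for AAE. The aquaporin genes PIP2-4 and PIP2-6, which encode water channels of the plasma membrane, were 18.5-fold and 3.88-fold higher. PIP2-4 was at 11.6 against 0.628, so its fold also rests on a low N18 level. AGA1 (GRMZM2G340656) was 15.1-fold higher, at 150.4 against 9.98; its locus is shared with another gene in the files, so its reads may be divided between them and its values are uncertain. ARGOS4 (GRMZM2G066029) rose 9.14-fold, ARGOS9 (GRMZM2G082943) 4.69-fold, opr5 6.63-fold, the beta-glucosidase gene glu1 5.11-fold, and C4ppdkZm1, the pyruvate orthophosphate dikinase gene of C4 photosynthesis, 4.41-fold. Under the same limits, the largest decreases were those of the MADS-box genes MADS34 (GRMZM2G137510), 6.14-fold, and m28 (GRMZM2G147716), 4.91-fold. They were followed, besides GRF9, ub3 and ub2 given above, by the SBP-box gene sbp29, 3.52-fold lower, the homeobox gene HB110, 3.24-fold lower, the ribosomal stalk gene rpp2a-4, 2.99-fold lower, and the chlorophyll-binding protein genes cab-m1 and cab48, 2.78-fold and 2.42-fold lower.

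The median log2 difference of the growth-regulating factor list was -0.46 on the log2(FPKM + 1) scale, below the central 95% of matched random lists (-0.14 to 0.09), and adjusted over the list alone 12 members passed as lower. Among 34 tested genes of ligule and leaf patterning, 6 were called lower and 1 higher, and adjusted over the list alone 8 and 1 passed. Among the lower ones were ub3 (GRMZM2G460544; chromosome 4, 199456663 to 199460958; 21.6 against 74.9), ub2 (GRMZM2G160917; chromosome 1, 188215375 to 188219483; 24.7 against 62.8), sbp29 and sbp27 (1.74-fold). The knotted-type homeobox gene lg3, called higher, was at 51.5 against 34.2, while its relative knox3 was lower, at 25.6 against 33.7, with an adjusted p of 0.018 in the authors' deposited table. Transcripts of KN-1 (180 against 172) and gnarley1 (27.3 against 27.0), homeobox genes of the shoot meristem and young stem, were not called. Of 34 jasmonate genes tested, 11 were called higher and 1 lower (adjusted over the list alone, 13 and 2), among them opr2 (2.88-fold), the allene oxide synthase gene aos1 (2.23-fold) and the lipoxygenase gene lox1 (2.18-fold). For heat shock genes 10 of 28 were higher and 0 lower (11 and 0 adjusted over the list alone), with hsp82 3.81-fold, Hsf26 2.86-fold and Hsf03 1.88-fold higher. Genes of abscisic acid perception and response gave 5 higher and 0 lower of 14 (7 and 1 adjusted over the list alone), including the receptor genes PYL5 (3.30-fold) and PYL7 (at 26.2 against 13.1). Defence genes gave 10 higher and 0 lower of 38 (12 and 0), with the benzoxazinoid gene bx6 at 437 against 248. Aquaporins gave 6 higher and 1 lower of 19 (7 and 2), and ethylene genes 4 higher and 0 lower of 27 (7 and 0), with EREB202 2.03-fold higher. The ethylene list was matched by name and takes in EREB and DBP transcription factor genes, so it does not measure ethylene synthesis or signalling alone. Medians of the jasmonate (0.13), heat shock (0.15), abscisic acid (0.29), defence (0.17), aquaporin (0.27), ethylene (0.21), cell wall loosening (0.15), homeobox leucine zipper (0.12) and phloem and sugar (0.17) lists lay above the central 95% of their matched random lists, and that of the ribosomal protein list (-0.09) below. In a two-sided permutation test over matched gene lists, 11 of the 25 lists passed in the internode after adjustment over the lists; phloem and sugar did not (adjusted p = 0.0608). Genes are not independent replicates, so this test describes the lists and not the plants.

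Gibberellin genes, which control stem elongation, were few by name. CYP88A1 (GRMZM2G093195; chromosome 9, 26725935 to 26729883), the kaurenoic acid oxidase gene of the dwarf3 locus, was at 13.7 in Sdw3 and 7.03 in N18, 1.95-fold higher, and eks1, a kaurene synthase gene, at 0.983 against 0.147 with an adjusted p of 0.0413 in the authors' deposited table. None of the 5 tested members of the list was called lower, and adjusted over the list alone 2 passed as higher and 1 as lower. The list's median was -0.09, of the opposite sign to its called members. The gibberellin 3-oxidase gene Dwarf1 was at 0.578 against 1.5 (adjusted p of 0.0691 in the authors' deposited table), an1 at 4.90 against 6.19, and the DELLA genes D8 (173 against 206) and d9 (50.4 against 47.1) were not called. All 8 brassinosteroid genes tested were uncalled, with 0 passing when adjusted over the list alone and 1 at an unadjusted p under 0.05 in the authors' deposited table. Cell cycle genes gave 1 higher and 2 lower of 33 (1 and 2 adjusted over the list alone), the lower ones being Rbl1 (29.0 against 37.4) and MCM6 (29.5 against 37.1), whose adjusted p in the authors' deposited table was 0.0077 and 0.0231. The higher one is by its name an inhibitor of the cell cycle, at 11.1 against 7.40, with an adjusted p of 0.0107 in that source. None of 11 histone genes and none of 13 lignin genes was called, 0 of either passed when adjusted over the list alone, and 0 and 3 had an unadjusted p under 0.05 in the authors' deposited table. CesA-3, a cellulose synthase gene, was lower at 44.9 against 60.1, with an adjusted p of 0.0139 in the authors' deposited table. In the remaining lists the members called higher and lower were 10 and 7 of 47 for auxin (13 and 9 adjusted over the list alone), 3 and 1 of 25 for cytokinin (4 and 1; crr2 was 2.27-fold higher), 3 and 2 of 16 for cell wall loosening (4 and 2; EXPA5 was 1.91-fold higher) and 0 and 1 of 15 for cellulose synthesis (0 and 1). For cytoskeleton they were 1 and 4 of 44 (1 and 4), for homeobox leucine zipper genes 4 and 1 of 26 (4 and 1), for photosynthesis 5 and 5 of 27 (6 and 6), and for epidermis and wax 2 and 0 of 12 (3 and 0). Floral MADS-box genes gave 1 and 4 of 11 (1 and 4), phloem and sugar genes 2 and 0 of 9 (4 and 0; incw1, a cell wall invertase gene, was 3.58-fold higher), and ribosomal protein genes 1 and 2 of 35 (1 and 2). Only combined values are in the files, so none of these internode calls could be checked library by library. Genes at 0 in one genotype have no fold here: 10 called internode genes were listed at 0 in Sdw3 and 13 at 0 in N18.

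**Figure D1:**
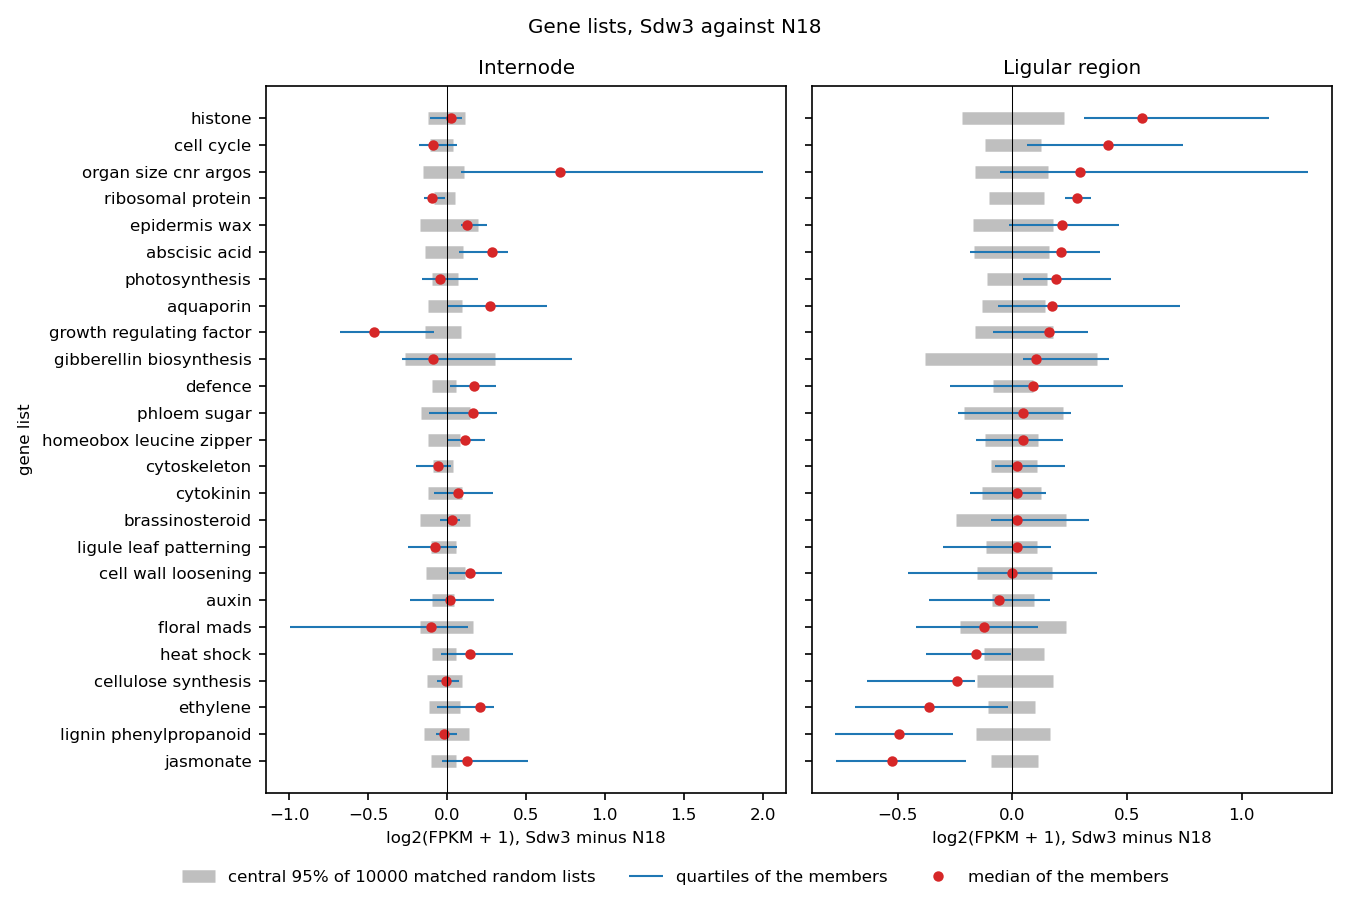
Median difference between Sdw3 and N18 in log2(FPKM + 1) for each gene list with at least 5 tested members (red points), with the quartiles of its members (blue lines) and the central 95% of 10000 random lists matched on expression (grey bars), in the internode (left) and the ligular region (right). The jasmonate list lies at 0.13 in the internode and -0.53 in the ligular region, and the growth-regulating factor list at -0.46 and 0.16.

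The second comparison asked the same of the ligular region. Jasmonate genes were lower there in Sdw3, with 27 of 42 tested members called lower and 2 higher (adjusted over the list alone, 28 and 2), and the list's median was -0.53. JAZ9 (GRMZM2G145407), one of the jasmonate-induced repressors of jasmonate response, was at 1.44 in Sdw3 and 8.08 in N18, 5.61-fold lower. Genes of lignin synthesis were also lower, 13 of 18 against 2 higher (13 and 2), with the laccase genes lac5 and Lac1 3.81-fold and 3.32-fold lower. By contrast 16 of 33 cell cycle genes were called higher and 1 lower (19 and 1), and 6 of 11 histone genes higher and 0 lower (6 and 1), with the histone H2B gene his2b2 at 128 against 49.7. The 16 cell cycle genes include the inhibitor gene that was also higher in the internode, here 1.48-fold higher with an adjusted p of 0.00259 in the authors' deposited table. Of 30 photosynthesis genes 11 were called higher, 1 lower and 18 not called; pep1 (GRMZM2G083841), the phosphoenolpyruvate carboxylase gene, was at 175 against 35.1 and the malic enzyme gene ME1 (GRMZM2G085019) at 73.9 against 16.7.

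The authors' deposited table called 6100 of 22721 ligular genes tested, 2985 higher and 3115 lower in Sdw3, of which 827 and 761 changed at least 2-fold. The median fold among called genes was 1.59. In this tissue the smallest adjusted p was 0.000398, shared by 2851 genes, and that is the value in the authors' deposited table of each ligular gene named in this and the next 2 paragraphs as called, unless another is given. Among called genes with a name and an FPKM of at least 5 in the higher genotype, the largest increases began with AAE, 22.2-fold, at 6.50 against 0.293, and ZAR1, 14.3-fold, at 15.6 against 1.09. With a pseudocount of 1 their order turned, with log2 ratios of 2.54 for AAE and 2.99 for ZAR1. The transcription factor gene bHLH35 rose 8.54-fold, the asparagine synthetase gene asn3 5.97-fold, Natterin-4 5.61-fold, NAC40 5.40-fold, the beta-expansin gene expB3 4.55-fold, OMT8 4.44-fold and ME1 4.41-fold. Under the same limits, the largest decreases were those of bHLH116 (GRMZM2G042895), 6.14-fold lower at 20.5 against 126, and PP2C13, a protein phosphatase 2C gene, lower at 1.65 against 9.91. After JAZ9 came bHLH108 (5.48-fold), MYBR95 (5.45-fold), the gene named both WRKY and WRKY53 (GRMZM2G125653; 5.20-fold), bss1 (5.05-fold), m28 (4.44-fold), the cytokinin oxidase gene CKX4b (3.90-fold) and lac5.

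Further jasmonate genes called lower included lox7 (2.90-fold), TIFY9 (2.79-fold) and ts1, a lipoxygenase gene needed for maleness of the tassel (2.53-fold). Ethylene genes gave 19 lower and 3 higher of 35 (20 and 3 adjusted over the list alone), with DBP4 2.96-fold and EREB65 2.93-fold lower. Both of these are transcription factor genes, so the counts do not show lower ethylene synthesis or signalling. An ethylene receptor gene of the same list was called higher, 1.40-fold in the internode and 1.26-fold in the ligular region. Its adjusted p in the authors' deposited table was 0.00109 and 0.0134. Cellulose synthesis genes gave 7 lower and 1 higher of 18 (9 and 1): the secondary wall cellulose synthase gene CesA12 was 2.27-fold lower, the brittle stalk gene bk2 2.78-fold lower and its relative Bk2L7 2.89-fold lower, while CSLD1 was 2.58-fold higher. Heat shock genes gave 9 lower and 1 higher of 27 (10 and 2), with Hsf03 2.09-fold lower. Medians of the ethylene (-0.36), lignin (-0.49), cellulose (-0.24) and heat shock (-0.16) lists lay below the central 95% of matched random lists, as did that of the jasmonate list. On the other side, ribosomal protein genes gave 18 higher and 1 lower of 36 (30 and 1), with arpp2a 1.51-fold higher, and the list's median was 0.28. The cyclin genes cyc3 and cyclin8 were 2.82-fold and 2.70-fold higher, although both stayed below an FPKM of 3, and the kinesin gene KIN8 was 3.17-fold higher at 2.69 against 0.849. Medians of the cell cycle (0.42), histone (0.56), ribosomal protein (0.28), photosynthesis (0.19), abscisic acid (0.21), aquaporin (0.17) and epidermis and wax (0.22) lists lay above the central 95% of matched random lists. For the photosynthesis list the counts adjusted over the list alone were 11 and 1, with C4ppdkZm1 1.98-fold higher at 476 against 240. After adjustment over the 25 lists, 13 passed in the permutation test over matched gene lists in the ligular region.

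Of 32 genes of ligule and leaf patterning, 3 were called higher and 7 lower in the ligular region (3 and 7 adjusted over the list alone), while the list's median was 0.02. The bZIP gene lg2 (GRMZM2G060216; chromosome 3, 176845303 to 176853978), needed for a normal ligule and auricle, was at 2.95 in Sdw3 and 0.925 in N18, 3.18-fold higher. Its partner in ligule formation, the SBP-box gene lg1 (GRMZM2G036297), was at 14.96 against 14.9 and was not called, with an adjusted p of 0.98 in the authors' deposited table. The homeobox gene knox8 was 4.37-fold lower at 0.636 against 2.78, YAB3 1.44-fold lower, and kan3 1.66-fold higher with an adjusted p of 0.00201 in the authors' deposited table. KN-1, knox3 and gnarley1 were listed at 0 in both genotypes there. CYP88A1 was at 65.0 against 105, 1.61-fold lower, and Dwarf1 at 1.53 against 0.557, 2.74-fold higher with an adjusted p of 0.0199 in the authors' deposited table, so the gibberellin list had 1 higher and 1 lower of 5 (1 and 1). Brassinosteroid genes gave 2 higher and 0 lower of 8 (1 and 0), one being Dwf4, 1.75-fold higher. Growth-regulating factors gave 4 higher and 1 lower of 16 (4 and 1), with atGRF5 (GRMZM2G105335) 2.53-fold higher. Remaining lists gave, as higher and lower, 6 and 14 of 47 for auxin (8 and 14 adjusted over the list alone; Yucca7, an auxin synthesis gene, was 3.88-fold higher), 3 and 5 of 26 for cytokinin (3 and 5, with a median of 0.02 that was -0.03 with quantile normalization), 7 and 2 of 16 for abscisic acid (7 and 2; PYL5 was 3.49-fold and PYL7 2.67-fold higher) and 6 and 7 of 20 for cell wall loosening (6 and 7; xth1 was 2.27-fold lower). Cytoskeleton genes gave 9 and 5 of 45 (9 and 5), homeobox leucine zipper genes 6 and 6 of 26 (6 and 6), epidermis and wax genes 5 and 2 of 14 (5 and 2; CER1 was 4.79-fold higher), and floral MADS-box genes 1 and 3 of 11 (1 and 4). Of those 3 lower genes, 1 was matched by name but is a floral gene outside the MADS-box family, 3.61-fold lower at 1.78 against 6.44. Phloem and sugar genes gave 2 and 3 of 11 (2 and 3), defence genes 21 and 13 of 56 (21 and 14; bx1, the first step of benzoxazinoid synthesis, was 6.76-fold higher) and aquaporins 9 and 2 of 23 (9 and 2). The DELLA genes D8 (201 against 204) and d9 (70.3 against 74.3) were not called here either. As in the internode, the calls rest on the authors' test and could not be checked library by library, and 9 called genes were listed at 0 in Sdw3 and 16 at 0 in N18.

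The third comparison asked which genes changed in both tissues. Several organ-size genes with ARGOS or ZAR names were higher in both. They belong to a list of the CNR and ARGOS families, drawn up only after the files had been seen but before any gene's level was read. In that list 6 of 12 tested were called higher and 1 lower in the internode, and 8 of 17 higher and 3 lower in the ligular region (8 and 1, and 8 and 3, adjusted over the list alone). The list pools the 2 families, so its counts and medians do not show that CNR genes were higher. The medians of this list were 0.72 and 0.30. ZAR3 (GRMZM2G137546) was 2.60-fold and 2.91-fold higher, ARGOS5 (GRMZM2G175995) 2.17-fold and 2.71-fold, ARGOS9 4.69-fold and 3.24-fold, and ARGOS4 9.14-fold and 2.83-fold, in the internode and the ligular region. PYL5, the abscisic acid receptor gene, was 3.30-fold and 3.49-fold higher. Lower in both were m28 (chromosome 7, 164451096 to 164456819; 4.91-fold and 4.44-fold), m4 (7.48-fold and 15.3-fold, at an FPKM of at most 4.74), bHLH116 (2.92-fold and 6.14-fold), CKX12 (3.31-fold and 2.08-fold) and PP2C13 (2.47-fold in the internode). Some of these folds rest on low values. CKX12 was at an FPKM of at most 1.51 in either tissue, with a ligular adjusted p of 0.045 in the authors' deposited table. In the internode bHLH116 was at 0.55 against 1.60, with an adjusted p of 0.0261 in that source. In the ligular region m4 was at 0.121 against 1.84. Across the 20099 genes tested in both tissues, 457 were called higher in both, where independent lists would share 162, and 209 lower in both, where they would share 111. Fisher's exact test (two-sided) over genes gave an odds ratio of 4.45 (p = 6.51e-108) for higher in both and 2.26 (p = 1.08e-20) for lower in both. Another 222 genes were higher in the internode and lower in the ligular region, where independent lists would share 153, and 130 genes went the other way, where they would share 117. For these, Fisher's exact test over genes gave odds ratios of 1.60 (p = 6.42e-09) and 1.14 (p = 0.187). Of the 1018 genes called in both tissues, 65.4% changed in the same direction. Across 20070 genes the log2 ratios of the tissues were weakly correlated (r = 0.21). The expectation for independent lists does not allow for genes that are easier to call in both tissues. Each tissue had its own N18 libraries by the labels, but whether the same plants gave both tissues is not stated there. Genes are not independent replicates, so these 4 p-values describe the gene lists and not the plants.

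The positions of genes called in the same direction in both tissues were examined in a scan chosen after the values were seen. Only windows with at least 15 genes tested in both tissues were scored. The stretch of chromosome 10 from 146 to 148 Mb held 15 such genes among 79 tested, 19.0% against 3.31% of all genes tested in both tissues, and 11 of the 15 were higher in Sdw3. It held crr2, a cytokinin response regulator gene (2.27-fold and 1.37-fold higher), and rpp2a-4, the ribosomal stalk gene (2.99-fold and 1.49-fold lower), and AAE lay just beyond its end. Among the 15, GRMZM2G043776 (higher) and GRMZM2G043903 (lower) have the same coordinates, so their reads may be divided between them. GRMZM2G142667 also shares a locus with another gene, and the count includes all of these. Chromosome 3 from 178 to 180 Mb held 9 among 33, 27.3%. In units of the standard deviation of a random count, the excess was 7.78 for the chromosome 10 stretch and 7.69 for the chromosome 3 stretch. The highest of 1000 random reassignments of the calls over all windows was 7.94. By that score both stretches lay below the highest random value, and how many reassignments reached their excess is not given here. By a binomial score, added after the first was seen, the stretches scored 7.34 and 6.05 against a highest random score of 5.29.

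**Figure D2:**
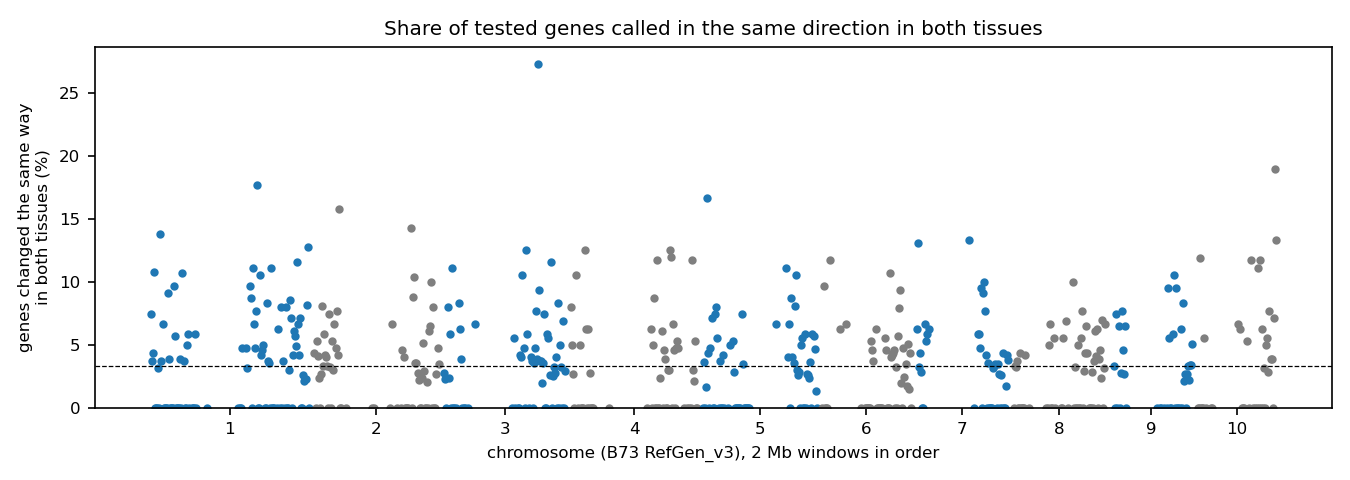
Percent of the genes tested in both tissues that were called in the same direction in both, in each of 592 windows of 2 Mb (points, with chromosomes side by side in 2 alternating colours). Windows with fewer than 15 genes tested in both tissues are left out. The dashed line is the share over all genes, 3.31%. The highest points are chromosome 3 from 178 to 180 Mb (27.3%) and chromosome 10 from 146 to 148 Mb (19.0%).

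**Figure D3:**
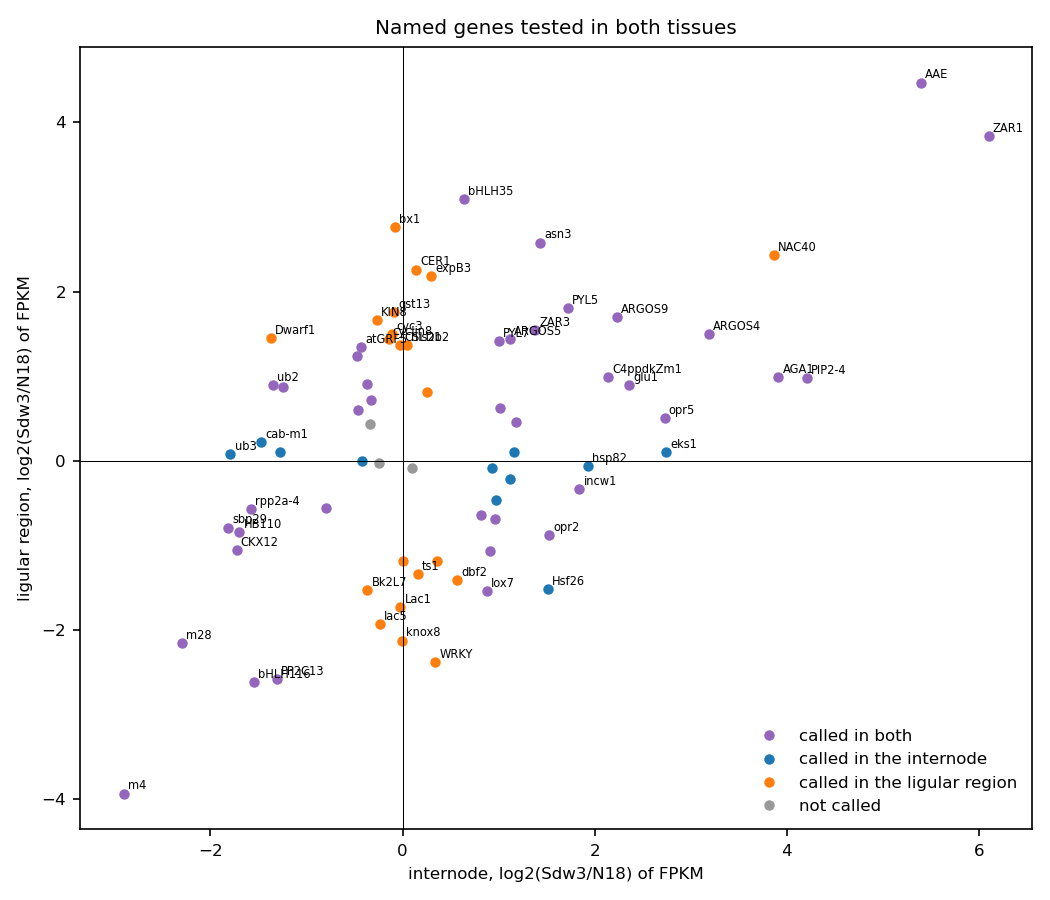
Log2 of the Sdw3 to N18 FPKM ratio in the internode (x axis) and the ligular region (y axis) for the 74 genes named in the text that were tested in both tissues; colour shows in which tissue the authors' deposited table calls the gene. AAE and ZAR1 lie at the upper right (5.40 and 4.47; 6.10 and 3.84), m28 at the lower left (-2.30 and -2.15), and ub2 is lower in the internode (-1.35) and higher in the ligular region (0.89).

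The last comparison asked whether the difference between Sdw3 and N18 depended on the tissue. The jasmonate genes lox7 and opr2 were called higher in the internode and lower in the ligular region, with a ligular minus internode difference in log2 ratio of -2.42 and -2.40. CYP88A1 likewise went in opposite directions (-1.65), as did Hsf03 (-1.97) and bx6 (-1.46). ub2 and GRF2 went the other way (2.24 and 2.12): they were lower in the Sdw3 internode and higher in the Sdw3 ligular region, where their adjusted p in the authors' deposited table was 0.00341 and 0.0101. Among named genes whose higher genotype reached an FPKM of 5 in both tissues, the largest positive differences were those of bHLH35 (2.46), expB3 (1.88), ub3 (1.87), gst13 (1.84), a glutathione transferase gene, and gar2 (1.72). The largest negative ones were PIP2-4 (-3.23), AGA1 (-2.92), ZAR1 (-2.26), opr5 (-2.22) and dbf2 (-1.98). Those of PIP2-4 and ZAR1 rest on N18 internode levels of 0.628 and 0.219, so their places in this order are uncertain. All of the differences named in this paragraph passed an adjusted p of 0.05 in an approximate normal test of the difference. Of 20070 genes with a ratio and an approximate standard error in both tissues, 3585 passed, 1750 with the larger log2 ratio in the ligular region and 1835 with the larger one in the internode (1776 and 1741 with quantile normalization, which turns the balance), and 352 of them were called in opposite directions. The standard error was derived from the authors' statistic and scaled to the authors' p-values; with the unscaled, larger standard error, an alternative chosen after the data were seen, 625 genes passed. No p-value of this test is given per gene, because the smallest ones lie far below the smallest p-value of 5e-05 in the authors' deposited table, from which the standard errors come.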

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

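The differences between the tissues come from the planned comparison, with a standard error chosen after the files were seen; the tests of less mature tissue, of a scale difference, of less dividing tissue and of floral tissue were chosen only after the results were seen.

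What singled these results out is that the effect of Sdw3 differed between the internode and the ligular region in a test of the difference itself. That held for 3585 of 20070 genes, and among the named genes, which were chosen partly for such differences, 56 of the 74 that could be tested passed, so that share says nothing about genes in general. With the unscaled, larger standard error, 625 of all genes and 43 of the named ones passed. Each value that follows is the ligular minus the internode log2 ratio of Sdw3 to N18. Among hormone and defence genes it was below 0 for the jasmonate genes opr5 (-2.22), opr2 (-2.40), lox7 (-2.42), ts1 (-1.49), lox1 (-1.34) and aos1 (-1.06), for the gibberellin genes CYP88A1 (-1.65) and eks1 (-2.63), and for crr2 (-0.72), bx6 (-1.46), glu1 (-1.46) and PP2C13 (-1.28). It was above 0 for Dwarf1 (2.83) and bx1 (2.84). No lower limit on FPKM was set for the genes listed here, and the values of Dwarf1 and eks1 rest on low levels. Dwarf1 was at an FPKM of at most 1.53 in either tissue and was not called in the internode. In the internode eks1 was at 0.983 against 0.147. Wall genes below 0 were lac5 (-1.69), Lac1 (-1.71), Bk2L7 (-1.16), CesA12 (-1.18), xth1 (-1.54) and EXPA5 (-1.02), while expB3 (1.88) and CSLD1 (1.39) were above. Every named cell cycle, histone, ribosomal and kinesin gene that passed lay above 0: Rbl1 (1.28), MCM6 (1.05), cyc3 (1.61), cyclin8 (1.58), his2b2 (1.33), arpp2a (1.06), rpp2a-4 (1.004) and KIN8 (1.93). Transcription factor genes above 0 were sbp29 (1.03), ub3 (1.87), ub2 (2.24), GRF2 (2.12), atGRF5 (1.77), HB110 (0.85) and bHLH35 (2.46), and those below were m16 (-1.43), knox8 (-2.12), dbf2 (-1.98), WRKY (-2.72), Hsf26 (-3.03) and Hsf03 (-1.97). Hsf26 was not called in the ligular region, at 1.34 against 3.84. Also below 0 were the organ-size genes ZAR1 (-2.26) and ARGOS4 (-1.69), and PIP2-4 (-3.23), incw1 (-2.18), AGA1 (-2.92), C4ppdkZm1 (-1.15) and hsp82 (-1.99). The remaining ones were cab-m1 (1.70), cab48 (1.38), asn3 (1.15), CER1 (2.12), gst13 (1.84) and gar2 (1.72).

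In the ligular region, cell cycle, histone and ribosomal protein genes were higher and jasmonate and lignin genes lower in Sdw3. Less mature tissue in the Sdw3 samples is a candidate explanation, but photosynthesis genes, which rise as a leaf matures, were higher too, at percentile 99.54 of matched random lists, which argues against it as the whole cause. The median log2 ratio of all tested genes was -0.001582, but the normalization between libraries is unknown and may itself set this median near 0. It therefore cannot decide whether the values of the genotypes differ by a single scale. Such a difference would move a list and its random lists alike, so it would not place lists beyond their matched ranges on both sides. Where along the leaf base each sample was taken is not in the labels used here, so a difference in position that brings both dividing and green tissue stays open and untested. An effect of the Sdw3 genotype on these tissues stays open as well, as an untested hypothesis.

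In the internode, growth-regulating factor genes and the SBP-box genes ub2, ub3 and sbp29 were lower in Sdw3. Less dividing tissue in the Sdw3 samples could lower them. The lower quartile of the cell cycle genes was -0.1778 against a median of -0.46 for the growth-regulating factors, so most cell cycle genes fell less. That comparison cannot exclude less dividing tissue, because the lists need not fall by the same amount with it. Among matched random lists the cell cycle list lay at percentile 9.39, the ribosomal protein list at 0.83 and the histone list at 75.19. Less dividing tissue therefore stays open. Floral or bud tissue in the N18 samples cannot be told apart from a genotype effect: the floral MADS-box list lay at percentile 12.87 of matched random lists, below the middle but not outside the central 95%. In that list MADS34 (6.14-fold) and m28 (4.91-fold) were called lower, and 4 of 11 members were called lower and 1 higher, m16 at 2.85 against 1.46. The list was matched by name, so its percentile is limited: it holds a floral gene outside the MADS-box family and lacks the MADS-box gene m4. Transcripts of m4 were 7.48-fold lower in the internode and 15.3-fold lower in the ligular region, at an FPKM of at most 4.74. In the ligular region m28 was lower too, 4.44-fold, which floral tissue in the internode samples could not cause. MADS34 was not tested there. An effect of the genotype on these genes stays open, untested beyond the calls themselves.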

How the results depend on the processing

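The unscaled standard error, the standard error from the p-value, the normal test in place of the authors' test, leaving out genes that share a locus, the pseudocount of 5 and the median shift for lists, and the pseudocount of 1 for named genes were chosen only after the data were seen. Requiring at least a 2-fold change left 462 called genes in the internode, 1588 in the ligular region, 1303 in the difference between tissues and 107 in the same direction in both, fewer by construction. An adjusted p of 0.01 left 391 in the same direction in both. For the difference between tissues, a mean FPKM of at least 5 left 2174 genes, with fewer genes tested, and the unscaled standard error 625, since it is larger. The other alternatives stayed within 1.5 times: 1800 to 2544 genes in the internode, 4479 to 6382 in the ligular region, 3080 to 3564 for the difference between tissues and 649 in the same direction in both. The balance of directions moved with scaling: in the internode 1637 genes were higher and 850 lower with the median shift (65.8% higher) and 1399 and 1103 with quantile normalization (55.9%). For the difference between tissues 1575 had the larger log2 ratio in the ligular region and 1989 in the internode with the median shift, and 1776 and 1741 with quantile normalization, so which side is larger depends on the scaling. Lists beyond their matched range numbered 11 to 13 in the internode and 13 in the ligular region with other pseudocounts and quantile normalization, while the median shift moves a list and its random lists alike and so tests nothing here. The phloem and sugar median in the internode fell inside the range with a pseudocount of 5 (0.10, percentile 96.7), and the cytoskeleton median left it with quantile normalization (-0.10, percentile 0.49); the cause was not tested. No called gene that is named and no list beyond its range changed direction under the alternatives run. Medians near 0, inside their range, changed sign under a scaling or pseudocount for the brassinosteroid, cell wall loosening and cytokinin lists in the ligular region and the cellulose, histone and lignin lists in the internode. Of 173 log2 ratios of named genes, 58 moved with a pseudocount of 1, as low values are drawn together, and 1, that of AAE in the internode, with a pseudocount of 0.1 (4.65) and with quantile normalization (4.87). No paired analysis was possible because the files hold 1 combined value per genotype and tissue, so the replicate numbers of the labels join no values. For the same reason the replicate block, leave-one-out, library weights, the planned test without trend, the estimated correlation between genes and other splits of the samples were not run, and the pseudocounts and a filter by library for counts of called genes were not run as planned. Unknown depth limits every value near 0, where a fold rests on few reads.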

Other observations

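All tests of position and of genes listed at 0 were chosen after the values were seen, and of these the tests of neighbouring genes and of parental origin were set before their own results were seen, while those of random placing and of copy number were chosen after.

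Some transcripts were listed at 0 in one genotype and at an FPKM of at least 1 in the other, in both tissues. There were 9 such genes, 4 at 0 in Sdw3 and 5 at 0 in N18, and 2 of the 9 lay in the stretches of chromosome 10 (140 to 150 Mb) and chromosome 3 (170 to 180 Mb), which hold 644 of 39514 genes. GRMZM2G045699 (chromosome 1, 228324145 to 228326276) was at 13.4 in the internode and 7.45 in the ligular region of Sdw3 and listed at 0 in N18. GRMZM2G701981 (chromosome 3, 177910123 to 177910612) was listed at 0 in Sdw3 and at 3.62 and 2.83 in N18. AC233788.2_FG002 (chromosome 8, 168969992 to 168970142), a very short model, was at 26918 and 15532 in Sdw3 and listed at 0 in N18, and the authors did not test it; it held 3.52% of the summed FPKM of the Sdw3 internode. All 3 were named after their values were seen.

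Stretches of chromosomes 10 and 3 held more genes called in the same direction in both tissues than the genome as a whole, and a hypothesis is that they differ in parental origin between Sdw3 and N18. Random placing is argued against on chromosome 10 in 10 Mb windows (an excess of 5.887 standard deviations against 5.779 in the highest of 1000 reassignments, binomial score 5.94 against 5.26) and by the 2 Mb binomial score (7.34 against 5.29) but not the 2 Mb excess (7.78 against 7.94), and on chromosome 3 by the 2 Mb binomial score alone (6.045 against 5.291; 2 Mb excess 7.69 against 7.94, 10 Mb excess 4.61 against 5.78, 10 Mb binomial score 3.80 against 5.26). An extra or missing copy of a whole 2 Mb stretch is argued against by the median log2 ratio of its tested genes, -0.0027 on chromosome 10 (95% interval -0.10 to 0.15 in the ligular region, -0.17 to 0.12 in the internode) and 0.0928 on chromosome 3 (-0.09 to 0.28 in the internode, -0.08 to 0.22 in the ligular region), while a copy change of a smaller segment stays open. Neighbouring genes called together, as tandem copies would be, stay open: with calls within 100 kb of a kept call dropped, the highest excess of a 10 Mb window was 3.791, within the random range (highest 6.593). Different parental origin also stays open: of internode calls not called in the ligular region, 70.59% (24 of 34) in the 10 Mb windows (chromosome 10 from 140 to 150 Mb and chromosome 3 from 170 to 180 Mb) kept the same sign there, against 51.82% (597 of 1152) elsewhere (Fisher's exact test, two-sided, p = 0.0361; genes are not independent replicates), and reads of one strain mapping worse to the reference could give the same picture, which was not tested.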
